A study of Homo sapiens with 57 samples.

How the data were processed

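MCF10A-ER-Src cells, a human breast epithelial line with a tamoxifen-inducible Src oncogene, were profiled by ribosome profiling (sequencing of the mRNA fragments protected by ribosomes) and by RNA-seq of poly(A) RNA. Cells were given ethanol as vehicle (EtOH, non-transformed) or 4-hydroxytamoxifen (TAM, transformed) for 24 h. They were then kept for 30 min in complete (Ctrl) or glutamine-free (NoQ) medium, or for 4 h in complete medium or in medium without glucose (NoG), glutamine, cysteine and cystine (NoCys) or the branched-chain amino acids leucine, isoleucine and valine (NoBCAA). TAM cells were also profiled with Torin1, an inhibitor of the mTOR kinase. The 57 samples form 28 groups, 32 libraries of ribosome profiling and 25 of RNA-seq. Groups were taken from the labels. Per the labels' protocols, lysates for ribosome profiling were made with cycloheximide and digested with RNase I, poly(A) RNA was fragmented with zinc chloride, and ribosomal RNA was removed from the cDNA with biotinylated probes.

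Reads were aligned with TopHat to genome build hg19, per the submitters' processing notes. The version, the counting tool, the filter on fragment length and the handling of reads that align to several places are not given in the sources used here. Values of genes with near-identical copies (ribosomal proteins, EEF1A1, histones, HSPA8, the SERPINB3 and SERPINB4 pair, SAA2) are uncertain for that reason. The deposited values are RPKM per gene, read counts scaled to coding length in kilobases and to library size, in a table of 6478 genes for 4 h and another of 5696 genes for 30 min; 5568 genes were in both. The RNA-seq values of 30 min are RPKM that the authors rounded to whole numbers, read here as a score of mRNA level. Per the file headers, the authors also deposited a p-value and a log2 fold of each starved library against a control library, and marks for genes they called higher or lower in ribosome occupancy or translation efficiency. Their test and thresholds are not given in the sources used here. Over 18 log2 fold columns of 4 h in the authors' deposited table, a median of 100% of genes equalled, within 0.1, the ratio to the Ctrl library with the same number; against Ctrl libraries with another number the median was 2.10%. Per-sample translation efficiency columns of the authors (32) and 2 RNA-seq columns of 30 min that no labelled sample covers were not used.

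Library depth was recovered from the steps between the deposited RPKM values of low genes, for 24 of 24 ribosome profiling libraries and 11 of 23 RNA-seq libraries of 4 h; on simulated tables the highest error was 0.0158%. At 30 min it was recovered only for ribosome profiling libraries numbered 1, and that depth stood for those numbered 2. The share of reads in the tabulated coding sequences is the sum over genes of RPKM times coding length, as a percentage of all reads behind the RPKM. Depths and shares are given with the results. PCR reads without molecular identifiers are not independent molecules, so counting error is a lower limit of the error.

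Ribosome occupancy and mRNA level were analysed as log2(RPKM + 1), a scale that understates changes of genes near 1 RPKM. Genes with at least 1 RPKM in at least 2 libraries were tested, 6478 for ribosome occupancy and 6476 each for mRNA level and translation efficiency. Tests used limma 3.58.1 in R 4.3.3 with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of adjusted p of 0.05. One mean per group was fitted over all 23 replicated ribosome profiling libraries of 4 h (22 for RNA-seq), so that groups of 2 or 3 libraries shared one estimate of the spread. Translation efficiency, the log2 ratio of ribosome profiling to RNA-seq, was tested as the difference of both contrasts in a single limma fit over both assays. There were 13 comparisons per measure: 4 starvations against Ctrl in each cell state, TAM against EtOH in Ctrl medium, and 4 tests of whether a starvation effect differed between cell states. Starvations within a cell state share their Ctrl libraries; EtOH and TAM comparisons share none. Errors given as ± after a log2 change are the standard errors from limma, and those after an RPKM mean are standard deviations between libraries. The labels do not say that replicates are separate cultures, so p-values measure the spread between these libraries. In ribosome occupancy without the block, standard errors hardly differed between genes, such as 0.43 for both STC1 and SRC in TAM against EtOH. They follow the intensity trend and not a gene's own spread, so a gene that is uneven between its libraries can be called. On simulated log2 values with 200 changed genes, log2 changes of 1, 2 and 3 were recovered in 13.4%, 92.5% and 100% of genes for ribosome occupancy of glutamine-starved EtOH cells. They were recovered in 77.6%, 98.5% and 100% for mRNA level, and in 5.97%, 61.2% and 97.0% for translation efficiency. False calls were 10, 10 and 4. Noise was drawn independently for each gene and library, so shifts of whole libraries or by library number, present in these data, are not covered.

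Gene lists (26, with 570 members of which 434 were in the 4 h table) were written before the data were examined, as were the tests, the alternatives and the rule for named genes. They covered inflammatory cytokines and chemokines, NF-kB feedback and target genes, interferon-stimulated genes, ATF4 target genes, cytosolic aminoacyl-tRNA synthetases, mRNAs with inhibitory upstream reading frames, ER chaperones and the unfolded protein response, cytosolic ribosomal proteins, other 5-prime TOP mRNAs, cholesterol biosynthesis, NRF2 targets, glycolysis, MondoA/ChREBP targets, immediate early genes, p53 targets, cell cycle genes, heat shock proteins, autophagy and lysosome genes, nuclear and mitochondrial genes of oxidative phosphorylation, STAT3 and Src response genes, histones, and markers of leukocytes, fibroblasts, luminal and basal cells. The 23 lists with at least 5 matched members were tested against all other genes with camera from limma at a preset inter-gene correlation of 0.01, adjusted over 299 tests per measure, and again with an estimated correlation. A gene that the deposited table places on chromosome Y was counted in its list, and its values are not given. The rule for named genes took, per starvation, up to 5 genes in each direction with the largest mean change in ribosome occupancy among those called in both cell states without overlap between libraries, filled with genes called in 1 state; 3 per direction for translation efficiency; up to 4 members per list; and ATF4, DDIT3, ASNS, CHAC1, TRIB3, IL6, IL8, CXCL1, IL1B, TXNIP, HMOX1, RPS6 and EEF1A1 always, with SRC for TAM against EtOH.

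Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling of the libraries, the library number as a block, translation efficiency as a ratio per library number, and leaving out each library in turn. The block together with scaling, and a fit of the ribosome profiling libraries numbered 2 and 3 only, were chosen after seeing the data. To see whether numbers pair the samples, deviations from the group means were correlated between libraries with the same number: where 3 numbers were shared, r was 0.30 to 0.42 for EtOH NoCys ribosome profiling, 0.18 to 0.25 for TAM against EtOH ribosome profiling and 0.26 to 0.77 for TAM against EtOH RNA-seq, so the numbers were taken to pair these samples. The pairing comes from these values, not from the labels, and the fits with the block had been run before this was settled. The main calls, errors and list tests leave the number out, as planned, and so ignore this pairing. Counts could change widely with the block, as for EtOH NoQ ribosome occupancy (64 and 366) and TAM against EtOH translation efficiency (0 and 96). The 30 min comparisons had been planned with the same limma test. The paired libraries of each 30 min group differed by a robust SD of at most 0.106 of that of counting error, so each pair was treated as 1 sample, and these data, like the single Torin1 libraries, are given as values without a test. Lists without a test were placed among 10000 random lists of the same size matched on mean expression. Numbers and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.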

Results

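Ribosome occupancy and mRNA level were measured in EtOH (non-transformed) and TAM (transformed) MCF10A-ER-Src cells kept in complete medium or without 1 nutrient. At 4 h each cell state had 3 Ctrl libraries per assay and 2 libraries each for NoG, NoQ and NoBCAA. NoCys had 3 ribosome profiling libraries in EtOH cells, 2 in TAM cells and 2 RNA-seq libraries in each state. Torin1 had 1 library per assay. At 30 min there were 2 ribosome profiling libraries each for Ctrl and NoQ in both states, and 1 RNA-seq library of NoQ per state. Depth at 4 h was 1.83 to 12.8 M reads for ribosome profiling, the lowest being the Torin1 library, and 8.0 to 16.0 M for the 11 RNA-seq libraries in which it could be recovered. The tabulated coding sequences held 20.6% to 31.5% of the reads in ribosome profiling libraries numbered 1, apart from 11.4% with Torin1, and 33.4% to 48.4% in those numbered 2 or 3. In RNA-seq libraries the share was 39.3% to 49.2%. Ctrl groups had libraries numbered 1, 2 and 3, NoQ groups 1 and 2, and NoG, NoBCAA and TAM NoCys groups 2 and 3, so the number was not balanced across starvations. Values from ribosome profiling libraries numbered 2 and 3 alone are therefore given beside the counts of genes.

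**Figure D1:**
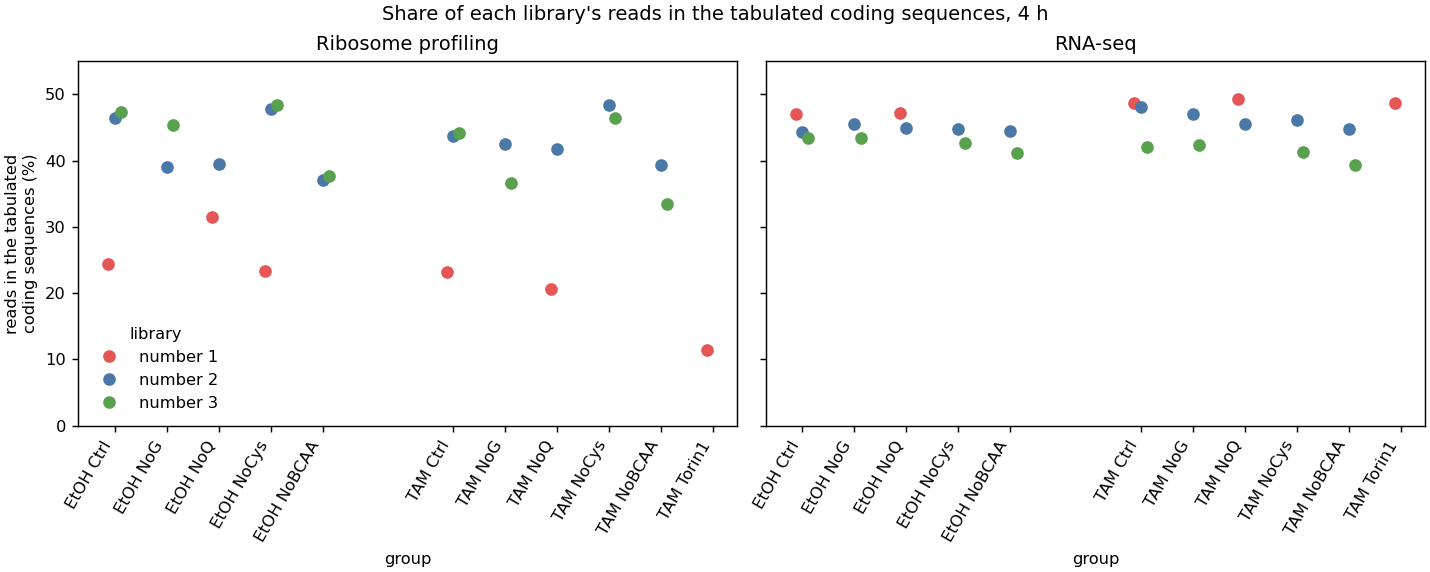
Percent of reads that fell in the tabulated coding sequences (vertical axis) in each 4 h library of ribosome profiling and RNA-seq, by cell state and medium, coloured by library number. Ribosome profiling libraries numbered 1 lie at or below 31.5% and those numbered 2 or 3 at or above 33.4%.

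The comparison of TAM with EtOH cells in complete medium asks what Src activation changed before any starvation. Transformed cells had higher ribosome occupancy of inflammatory cytokines and chemokines as a list, and single genes changed by far more. STC1, a secreted glycoprotein hormone (hg19 chromosome 8, 23699434 to 23712320), rose by 8.30 ± 0.43 on the log2 scale. Its mean went from 5.53 to 1717 RPKM (n = 3 per state, adjusted p = 1.1e-79 by limma, and 9.0e-10 with the block and scaling). The cytokine IL24 rose by 7.36 ± 0.42, the protease inhibitors SERPINB4 and SERPINB3 by 7.50 ± 0.42 and 6.59 ± 0.43, and the metalloproteinase ADAMTS4 by 5.95 ± 0.39. CLDN1, a tight junction claudin, fell by 4.25 ± 0.41, and the epithelial transcription factor GRHL3 and the ectonucleotidase ENTPD2 each fell by 3.21 ± 0.38. The matrix protein THBS1 fell by 3.11 ± 0.44. The mRNAs of all these genes changed in the same direction, such as STC1 by 5.99, IL24 by 6.20, CLDN1 by −3.70 and THBS1 by −3.15. None of them was called in translation efficiency, so changes in ribosome loading were not shown apart from mRNA level. For each of these genes the 3 TAM libraries lay beyond all 3 EtOH libraries, because the rule that named genes for this comparison required it. SRC itself differed by 0.03 ± 0.43 (adjusted p = 0.98) and its mRNA by −0.17, and these levels do not measure Src activity. Of 6478 genes, 238 rose and 141 fell in ribosome occupancy, 468 and 1596 with the library number as a block, and 404 and 1091 in libraries numbered 2 and 3. After scaling 696 rose and 424 fell, and 772 and 539 with the block and scaling, so which direction prevailed depended on the setting. For mRNA level 643 rose and 1649 fell, 934 and 2814 with the block, and 983 and 858 after scaling, and 1557 and 1616 with the block and scaling. The median of all genes was −0.31 for ribosome occupancy and −0.20 for mRNA, and list medians are given relative to the median of all genes of their comparison throughout. Chance alone leaves 10% of genes without overlap at 3 against 3; 311 were higher and 384 lower in ribosome occupancy without overlap. Without EtOH Ctrl library 1, 634 genes were called.

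By gene group, 9 of 18 inflammatory cytokines and chemokines rose in ribosome occupancy and 2 fell (9 and 2 adjusted over the list alone; list median 1.52, adjusted p = 3.8e-14, and adjusted p = 0.02 with an estimated correlation). CCL2 rose by 3.51 ± 0.39, CXCL3 by 3.77 ± 0.43 and CXCL1 by 1.63 ± 0.43, whereas CXCL10 was among the 2 that fell (adjusted p = 6e-09). IL6, IL8 and IL1B were not called, at 0.58, 0.58 and 0.06; with the block and scaling IL8 was (0.89, adjusted p = 0.0038). Of 14 STAT3 and Src response genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 1.63, adjusted p = 2.1e-14, and adjusted p = 0.14 with an estimated correlation). Among them were the cytokine signalling inhibitor SOCS3 at 4.68 ± 0.41 and the acute phase gene SERPINA3 at 3.89. Interferon-stimulated genes had a median of 1.64, with 5 of 9 called higher (6 adjusted over the list alone; adjusted p = 6.8e-09, and adjusted p = 0.14 with an estimated correlation). IFI27 was at 3.38 ± 0.40 and ISG15 at 1.49. For mRNA level 7 of these 9 rose (7 adjusted over the list alone) and the list call held with an estimated correlation (adjusted p = 0.043). NF-kB feedback and target genes had 5 of 13 higher (6 higher and 1 lower adjusted over the list alone; median 1.17, adjusted p = 8.4e-05, and adjusted p = 0.66 with an estimated correlation). Glycolysis had a median of 0.57 (2 of 20 higher, 4 adjusted over the list alone; adjusted p = 0.00031, and adjusted p = 1 with an estimated correlation). The members called were the glycolytic regulators PFKFB3 at 2.98 ± 0.41 and PFKFB4 at 1.96. With the block and scaling SLC2A1 (1.47, adjusted p = 0.0002) and ALDOC (1.35, adjusted p = 0.0018) were called higher too. Of 23 cell cycle genes 22 fell in mRNA (22 adjusted over the list alone; median −0.60, adjusted p = 2.1e-07, and adjusted p = 0.39 with an estimated correlation), such as the replication clamp PCNA by −0.93 ± 0.12. In ribosome occupancy the list was lower (median −0.41, adjusted p = 0.016, and adjusted p = 1 with an estimated correlation). No single member was called, but with the block and scaling PCNA, UBE2C, CCNA2 and CCNB2 were among those called lower (−0.64 to −0.53, adjusted p = 0.0065 to 0.036). Autophagy and lysosome genes had a relative median of 0.29 in ribosome occupancy (2 of 13 higher; adjusted p = 0.002, and adjusted p = 1 with an estimated correlation). The cathepsins CTSL1 and CTSB rose by 3.70 ± 0.44 and 3.40, while the list median as measured was −0.01 and its mean 0.56. Luminal markers had 2 of 7 lower, CLDN4 among them at −3.02 ± 0.38; their test called the list lower (adjusted p = 0.033, and adjusted p = 1 with an estimated correlation) although the relative median was 0.11. Basal markers (1 of 13 higher, KRT6A at 1.64) and fibroblast and mesenchymal markers (1 of 5 higher, DCN at 1.33) were not called as lists. With the block and scaling the fibroblast markers POSTN (1.38) and FAP (1.14) and the basal markers COL17A1 (0.83) and LAMB3 (0.75) were also called higher. The basal marker EGFR was then called lower (−0.65; adjusted p of these genes 3.6e-05 to 0.0076). Of the leukocyte markers, too few to test, CD68 rose by 1.51. Of 20 NRF2 targets 1 rose (HMOX1, heme oxygenase, at 2.22) and 4 fell, including GCLC at −1.85 and the cystine transporter SLC7A11 at −1.34, with no list call (adjusted p = 0.11).

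Glutamine starvation for 4 h asks how the cells respond to the loss of a single amino acid. In both cell states genes of the ATF4 response rose steeply. CHAC1, an enzyme that degrades glutathione (hg19 chromosome 15, 41245636 to 41248717), rose by 5.61 ± 0.44 in EtOH and 4.44 ± 0.44 in TAM cells (n = 2 against 3, adjusted p = 3.9e-33 and 6.2e-20). The pseudokinase TRIB3 rose by 4.08 ± 0.45 and 3.20 ± 0.45, the secreted hormone STC2 by 4.03 ± 0.48 and 3.18 ± 0.48, and the transcriptional regulator TSC22D3 by 2.63 ± 0.46 and 3.22 ± 0.46. Ribosome occupancy of ATF4 itself, a transcription factor of amino acid stress, went from 23.1 ± 2.7 to 265.6 ± 17.2 RPKM in EtOH cells (log2 3.47 ± 0.48) and rose by 3.18 ± 0.48 in TAM cells. Its mRNA rose by 1.29 ± 0.20 and 1.15 ± 0.20. Decreases called in both states included NETO2, a receptor accessory protein, at −1.77 ± 0.44 and −1.57 ± 0.44; HSPA8, a constitutive chaperone, was at −1.94 ± 0.49 in EtOH and at −1.60 (adjusted p = 0.081) in TAM cells. In EtOH cells 60 genes rose and 4 fell, or 256 and 148 after scaling; the others of the 4, CAMK2N1 at −1.80 and CCDC85B at −1.63, are named because they were called, after their values were seen. In TAM cells, where the median of all genes was −0.33, 35 rose and 15 fell, or 306 and 166 after scaling. With the library number as a block 161 rose and 703 fell there, and 416 and 284 with the block and scaling. In libraries numbered 2 alone against Ctrl libraries 2 and 3 the counts were 52 and 28 in EtOH and 50 and 20 in TAM cells. For mRNA 427 rose and 289 fell in EtOH, and 290 and 210 in TAM cells. With the block decreases prevailed, at 796 up and 1032 down in EtOH and 581 and 930 in TAM cells, and with the block and scaling the counts were 912 and 901, and 710 and 754. HSPA8 in TAM cells was called with the block and scaling (−1.18, adjusted p = 0.00032). Without NoQ library 1 the counts in EtOH cells were 21 for ribosome occupancy and 225 for mRNA. In TAM cells ribosome occupancy gave 360 without NoQ library 2 and 131 without Ctrl library 1. It gave 26, 29 and 26 without NoQ library 1, Ctrl library 2 and Ctrl library 3, and mRNA gave 131, 292 and 324 without the same 3.

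**Figure D2:**
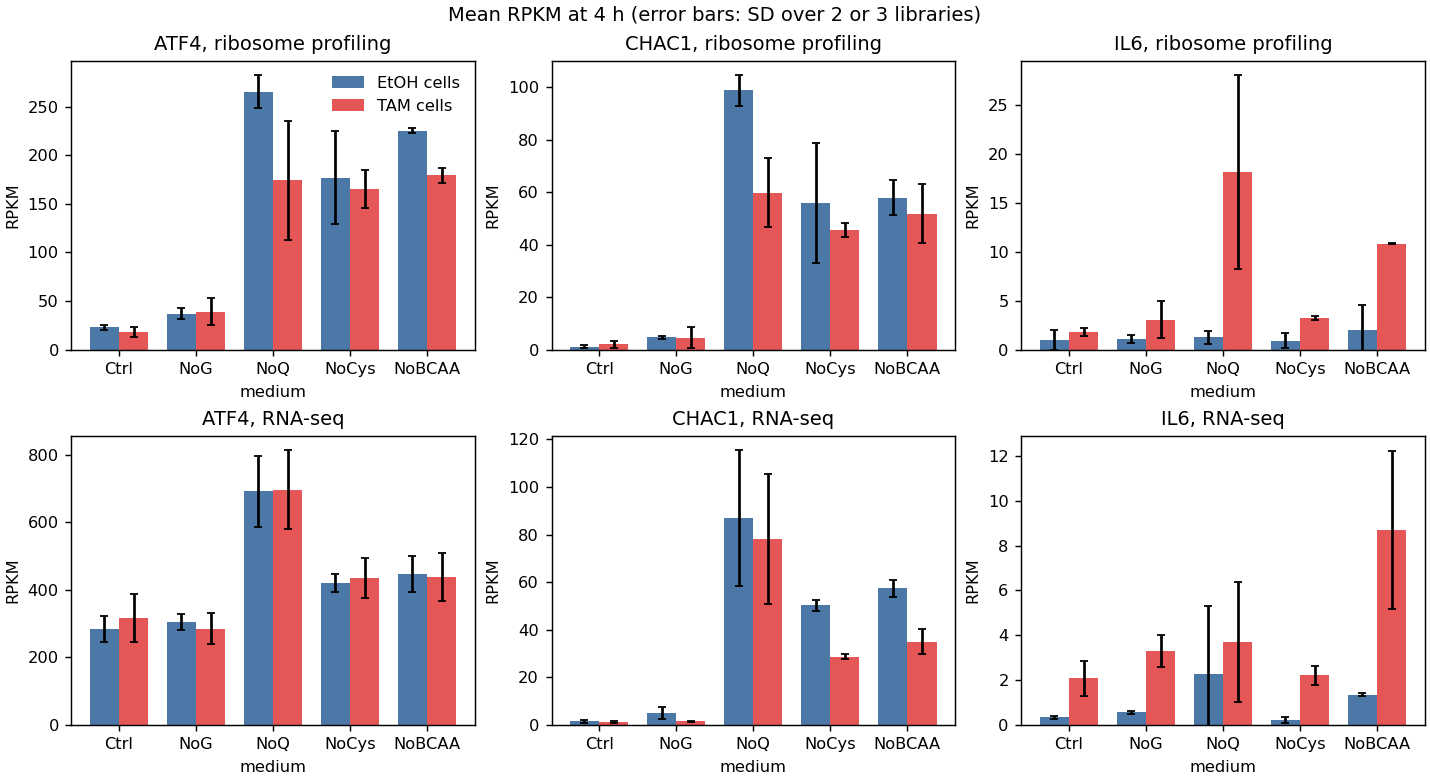
Mean RPKM of ATF4, CHAC1 and IL6 (vertical axes) by ribosome profiling, top, and RNA-seq, bottom, in 5 media at 4 h for EtOH and TAM cells; error bars are the standard deviation of 2 or 3 libraries. ATF4 ribosome occupancy is 23.1 in EtOH Ctrl and 265.6 in EtOH NoQ, whereas its mRNA is 282.8 and 692.2.

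Of 34 ATF4 targets, 17 rose in ribosome occupancy without glutamine in EtOH cells and 11 in TAM cells, with 0 lower (24 and 19 adjusted over the list alone; medians 1.70 and 1.64, adjusted p = 6.1e-88 and 1.3e-64). Both list calls held with an estimated correlation. Their mRNAs rose in 30 and 28 cases and fell in 1 each (32 and 30 up adjusted over the list alone), such as asparagine synthetase ASNS by 3.20 and 3.61. Cytosolic aminoacyl-tRNA synthetases, which load amino acids on tRNA, had mRNA medians of 0.68 and 0.95 (10 of 19 higher and 1 lower in each state; 10 and 12 higher adjusted over the list alone; adjusted p = 4.5e-06 and 1.8e-10, held with an estimated correlation). CARS mRNA, for instance, rose by 1.72 and 1.87. Inflammatory cytokines and chemokines rose as a list in ribosome occupancy in both states, with 7 of 18 genes called in EtOH and 6 in TAM cells (11 and 10 adjusted over the list alone). Their medians were 1.41 and 1.57 (adjusted p = 2.1e-21 and 8e-37, held with an estimated correlation at 0.011 and 0.0026). The cytokine LIF rose by 2.47 ± 0.44 and 3.09 ± 0.44, the prostaglandin synthase PTGS2 by 2.19 ± 0.46 and 1.98, and IL8 by 1.77 in EtOH cells (1.42, adjusted p = 0.15, in TAM cells). IL6 rose by 2.70 ± 0.43 in TAM cells and stood at 0.27 ± 0.43 in EtOH cells, with the difference between states not called (2.44 ± 0.61, adjusted p = 0.21); CXCL1 and IL1B were not called in either state. With the block and scaling IL8 and IL1B were called in TAM cells (1.46 and 1.16, adjusted p = 0.00047 and 0.0066). At the mRNA level the list was also higher (5 and 6 genes, 7 and 6 adjusted over the list alone; medians 1.29 and 0.87; adjusted p = 5.2e-06 and 4.9e-05, and adjusted p = 0.41 and 0.47 with an estimated correlation). NF-kB feedback and target genes had medians of 0.96 and 1.29 in ribosome occupancy (0 and 2 of 13 genes, 4 and 7 adjusted over the list alone; adjusted p = 6.3e-10 and 2.3e-16, and adjusted p = 0.17 and 0.049 with an estimated correlation). Immediate early genes rose as a list in EtOH cells (3 of 20 genes, 5 adjusted over the list alone; median 0.82, adjusted p = 5.3e-16, and adjusted p = 0.27 with an estimated correlation). KLF4, an epithelial transcription factor, rose by 2.95. Heat shock protein mRNAs were lower (5 of 11 in EtOH and 2 in TAM cells, 6 and 3 adjusted over the list alone; medians −0.81 and −0.45; adjusted p = 6.4e-05 and 0.0021, and adjusted p = 0.36 and 0.47 with an estimated correlation). Of 12 p53 targets, 5 and 4 mRNAs rose (medians 0.44 and 0.30, adjusted p = 0.00099 and 0.0027, and adjusted p = 0.47 and 0.53 with an estimated correlation), including the apoptosis regulator PMAIP1 by 2.44 and 2.66. TXNIP, a glucose-responsive MondoA/ChREBP target, rose by 2.62 ± 0.46 in EtOH cells and stood at 0.99 in TAM cells (1.23 with the block and scaling, adjusted p = 0.016); that list, with TXNIP and KLF10 measured, was too small to test.

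Starvation for branched-chain amino acids asks the same for leucine, isoleucine and valine. CHAC1 rose by 4.84 ± 0.44 in EtOH and 4.23 ± 0.44 in TAM cells (n = 2 against 3, adjusted p = 3.4e-24 and 5.9e-18). The stress transcription factor DDIT3 rose by 4.07 ± 0.43 and 3.74, TRIB3 by 3.72 and 3.85, and PPP1R15A, which directs dephosphorylation of eIF2-alpha, by 3.79 and 2.84. ATF4 rose by 3.23 ± 0.48 and 3.26 ± 0.48 in ribosome occupancy, with its mRNA at 0.67 ± 0.20 (called) and 0.48 (adjusted p = 0.12), the latter called with the block and scaling (0.73, adjusted p = 0.00014). HSPA8 fell by 2.17 ± 0.49 and 1.86 ± 0.49, and its mRNA fell by 2.48 ± 0.24 and 1.43. EIF4EBP2, a repressor of cap-dependent translation, fell by 2.12 ± 0.45 in EtOH cells and was at −1.47 (adjusted p = 0.13) in TAM cells, where the block and scaling called it (−1.47, adjusted p = 0.00058). Counts were 78 up and 14 down in EtOH cells, or 473 and 360 after scaling, and 34 up and 3 down in TAM cells, or 237 and 130 after scaling. In libraries numbered 2 and 3 they were 243 up and 1216 down, and 109 up and 691 down. With the block and scaling they were 588 up and 474 down, and 327 up and 205 down. For mRNA 522 rose and 479 fell in EtOH cells, or 937 and 1233 with the block and 1065 and 1073 with the block and scaling. In TAM cells 330 rose and 650 fell, or 638 and 429 after scaling, 694 and 1777 with the block and 1074 and 1048 with the block and scaling. The 3 that fell in TAM cells were HSPA8, PAX3 and SLCO1A2, the latter pair in libraries numbered 1 only, as given with the cysteine results. Without NoBCAA library 2 or 3, ribosome occupancy gave 43 and 30 calls in EtOH cells and 17 each in TAM cells, where 20 were called without Ctrl library 1. For mRNA the counts without these NoBCAA libraries were 512 and 346 in EtOH cells, and in TAM cells 241 without NoBCAA library 3 and 572 without Ctrl library 2.

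Without branched-chain amino acids, 14 of 34 ATF4 targets rose in ribosome occupancy in each state (21 and 23 adjusted over the list alone; medians 1.31 and 1.37; adjusted p = 3.9e-46 and 1.5e-71, and adjusted p = 0.054 and 0.018 with an estimated correlation). Of their mRNAs 29 of 34 rose in each state. The mRNAs with inhibitory upstream reading frames, which are translated when initiation is limited, had 4 of 7 called higher in ribosome occupancy in each state (5 higher and 1 lower, and 4 higher, adjusted over the list alone). Their medians were 1.90 and 2.43 (adjusted p = 2.2e-19 and 5.9e-25, held with an estimated correlation). Aminoacyl-tRNA synthetase mRNAs rose in 9 and 11 of 19 cases and fell in 1 each (11 and 12 higher adjusted over the list alone; medians 0.54 and 0.85; adjusted p = 5.2e-06 and 7e-09, held with an estimated correlation). Inflammatory genes had medians of 1.25 and 0.89 in ribosome occupancy (6 and 3 of 18, 12 and 7 adjusted over the list alone; adjusted p = 2.2e-19 and 9.8e-13, held with an estimated correlation at 0.011 and 0.029). LIF rose by 3.20 ± 0.44 and 2.79, PTGS2 by 3.13 ± 0.46 and 2.02, and CXCL3 by 2.39 in EtOH cells, while IL6 rose by 2.11 ± 0.43 in TAM cells and was at 0.45 in EtOH cells. Neither IL8, CXCL1 nor IL1B was called in ribosome occupancy in either state. With the block and scaling IL8 (adjusted p = 6.7e-05 and 0.00049) and IL1B (adjusted p = 8.2e-05 and 0.00013) were called higher in EtOH and TAM cells. Immediate early genes had medians of 0.79 and 0.69 (2 and 1 of 20 higher, 5 in each adjusted over the list alone; adjusted p = 3.8e-08 and 3.1e-09, and adjusted p = 0.71 and 0.65 with an estimated correlation). Heat shock mRNAs were lower (7 and 6 of 11, 9 and 6 adjusted over the list alone; medians −0.70 and −0.57; adjusted p = 1.9e-05 and 0.0011, and adjusted p = 0.31 and 0.46 with an estimated correlation). The co-chaperone DNAJA1 was at −1.79 and −1.57 in mRNA. Glycolysis mRNAs fell in 5 and 11 of 20 cases (6 and 12 adjusted over the list alone; medians −0.16 and −0.34; adjusted p = 0.01 and 0.00015, and adjusted p = 0.6 and 0.41 with an estimated correlation). Cholesterol biosynthesis mRNAs fell in 4 and 5 of 23 cases, such as NSDHL at −1.41 and −1.40. The list was called in EtOH cells (median −0.21, adjusted p = 0.042, and adjusted p = 0.84 with an estimated correlation) and not in TAM cells (adjusted p = 0.081). Cell cycle mRNAs fell in 8 and 5 of 23 cases (list called in EtOH cells, median −0.27, adjusted p = 7.4e-06, and adjusted p = 0.46 with an estimated correlation), with PCNA at −1.15 and −1.12.

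Cysteine starvation asks how cells respond to the loss of the amino acid that limits glutathione synthesis, and it also raised genes of the ATF4 response. CHAC1 rose by 4.70 ± 0.40 in EtOH cells (n = 3 against 3, adjusted p = 7e-29) and 4.07 ± 0.44 in TAM cells (n = 2 against 3, adjusted p = 1.9e-16). ATF4 rose by 2.85 ± 0.43 and 3.14 ± 0.48 in ribosome occupancy. Its mRNA was not called (0.58 and 0.48), except with the block and scaling (0.71 and 0.64, adjusted p = 0.0015 and 0.0046). STC2 rose by 2.57 and 2.78, ASNS by 2.24 and 2.67, and the glycine transporter SLC6A9 by 1.78 and 2.10; DDIT3 was not called. Of 34 ATF4 targets 9 and 12 rose (18 and 24 adjusted over the list alone; medians 1.09 and 1.00; adjusted p = 1.8e-66 and 4.2e-85, held with an estimated correlation). Aminoacyl-tRNA synthetase mRNAs rose in 7 and 8 of 19 cases (11 in each adjusted over the list alone; medians 0.49 and 0.51; adjusted p = 7.3e-14 and 1.9e-22, held with an estimated correlation). SLC7A11, which imports cystine, rose by 1.95 in TAM cells and was at 1.04 in EtOH cells (1.07 with the block and scaling, adjusted p = 0.0033). HMOX1 was at 1.76 ± 0.43 in TAM cells (adjusted p = 0.023), and its call ended with the block and scaling (1.14, adjusted p = 0.79). NRF2 targets had 2 of 20 higher there and no list call (adjusted p = 0.081). Inflammatory genes had 0 of 18 called in either state by limma (2 in EtOH cells adjusted over the list alone). As a list they were higher in EtOH cells, at 0.52 (adjusted p = 9.4e-09, and adjusted p = 0.094 with an estimated correlation). In TAM cells, where the median of all genes was 0.36, they were called lower, at −0.28 (adjusted p = 0.0032, and adjusted p = 0.71 with an estimated correlation); the list median as measured was 0.08, and with the block the adjusted p was 0.56. Counts were 10 up and 0 down in EtOH cells with limma, where 167 genes had an unadjusted p under 0.05. They were 37 and 7 with the block, 42 and 2 in libraries numbered 2 and 3, and without NoCys libraries 1 and 2 in turn 29 and 6 in all. In TAM cells 14 rose and 2 fell, or 22 and 0 after scaling, 19 and 0 with the block and 17 and 0 in libraries numbered 2 and 3. The 2 that fell, PAX3 and SLCO1A2, were at 10.3 to 182.3 and 10.9 to 268.3 RPKM in ribosome profiling libraries numbered 1 and at most at 0.4 and 0.2 in all others, and TAM NoCys had no library numbered 1. For mRNA 33 rose and 0 fell in EtOH cells, and 28 and 0 in TAM cells, with 431 and 241 genes at an unadjusted p under 0.05. In TAM cells 6, 4 and 6 genes were called in ribosome occupancy without NoCys library 2, NoCys library 3 and Ctrl library 1. The mRNA counts were 11 in EtOH and 12 in TAM cells without NoCys library 3, and 17 in TAM cells without NoCys library 2.

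Glucose starvation asks how cells respond to the loss of a sugar rather than an amino acid. It raised mRNAs of ER chaperones, proteins that fold secreted proteins, while few ATF4 targets were called. Of 20 ER chaperone and unfolded protein response genes, 8 mRNAs rose in EtOH and 9 in TAM cells (9 and 17 adjusted over the list alone; medians 0.54 and 0.92; adjusted p = 1.4e-16 and 3.1e-33, held with an estimated correlation at 0.00016 and 2.4e-05). The chaperone HSPA5 rose by 1.29 ± 0.17 and 1.60 ± 0.17 in mRNA (n = 2 against 3, adjusted p = 0.00079 and 0.00014), HERPUD1, of ER-associated degradation, by 1.63 ± 0.17 and 1.23, and SDF2L1 by 1.15 and 1.28. In ribosome occupancy the list was higher by 0.25 and 0.84 with 0 genes called (0 and 5 adjusted over the list alone; adjusted p = 1.7e-05 and 4.1e-25, and adjusted p = 1 and 0.14 with an estimated correlation). ATF4 stood at 0.65 and 1.05 in ribosome occupancy, not called except in TAM cells with the block and scaling (1.06, adjusted p = 0.017). ATF4 targets had relative medians of 0.03 and 0.15 (called as a list in TAM cells, adjusted p = 0.038, and adjusted p = 1 with an estimated correlation). Of their mRNAs 4 of 34 rose and 2 fell in EtOH cells, and 1 rose in TAM cells. OGT, the enzyme that attaches the glucose-derived sugar GlcNAc to proteins, rose in ribosome occupancy by 1.96 ± 0.43 and 1.78 ± 0.43 (adjusted p = 0.023 and 0.042) while its mRNA was at −0.10 and 0.52. In translation efficiency limma called 0 genes without glucose in either state. The matricellular gene CTGF rose by 2.12 ± 0.47 in EtOH cells and was at 1.43 in TAM cells (1.26 with the block and scaling, adjusted p = 0.026), with mRNA up by 2.17 and 1.75. TXNIP mRNA fell by 1.79 ± 0.31 in TAM cells and was at −0.99 (adjusted p = 0.067) in EtOH cells (−0.66 with the block and scaling, adjusted p = 0.024). Interferon-stimulated mRNAs were lower in TAM cells (median −0.43, 0 genes called by limma and 2 adjusted over the list alone, adjusted p = 0.0073, and adjusted p = 0.4 with an estimated correlation). IL6, IL8, CXCL1 and IL1B were not called, except the mRNAs of IL8 and IL1B in EtOH cells with the block and scaling (1.62 and 0.78, adjusted p = 0.0046 and 0.01). In ribosome occupancy 3 rose and 1 fell in EtOH cells (3 and 9 in libraries numbered 2 and 3), and 4 and 4 in TAM cells (22 and 11 after scaling, 13 and 42 in libraries numbered 2 and 3). With the block and scaling 14 rose and 7 fell in EtOH and 47 and 36 in TAM cells. The others called were IFFO2 in EtOH cells, which rose, and in TAM cells ZNF644, IVNS1ABP and TM4SF19, which rose, and RGS16 and GAS1, which fell. SLCO1A2 fell in EtOH cells and PAX3 and SLCO1A2 in TAM cells, and NoG had no library numbered 1. TM4SF19 is named after its values were seen. At a pseudocount of 0.1, 1 of the 4 main calls in EtOH cells and 1 of the 8 in TAM cells were kept. For mRNA 40 rose and 367 fell in EtOH cells, or 63 and 149 after scaling, and 43 rose and 57 fell in TAM cells. With the block 353 rose and 1368 fell in EtOH and 167 and 339 in TAM cells, while with the block and scaling 808 and 943, and 231 and 260, were nearly even. These counts turned on single libraries: ribosome occupancy gave 0, 0 and 1 calls in EtOH cells without NoG library 2, NoG library 3 and Ctrl library 1. In TAM cells it gave 0, 1, 3 and 2 without NoG library 2, NoG library 3, Ctrl library 1 and Ctrl library 2. EtOH mRNA gave 1188, 11, 124 and 219 without NoG library 2, NoG library 3, Ctrl library 1 and Ctrl library 3. TAM mRNA gave 26, 7, 33 and 64 without NoG library 2, NoG library 3, Ctrl library 2 and Ctrl library 3.

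**Figure D3:**
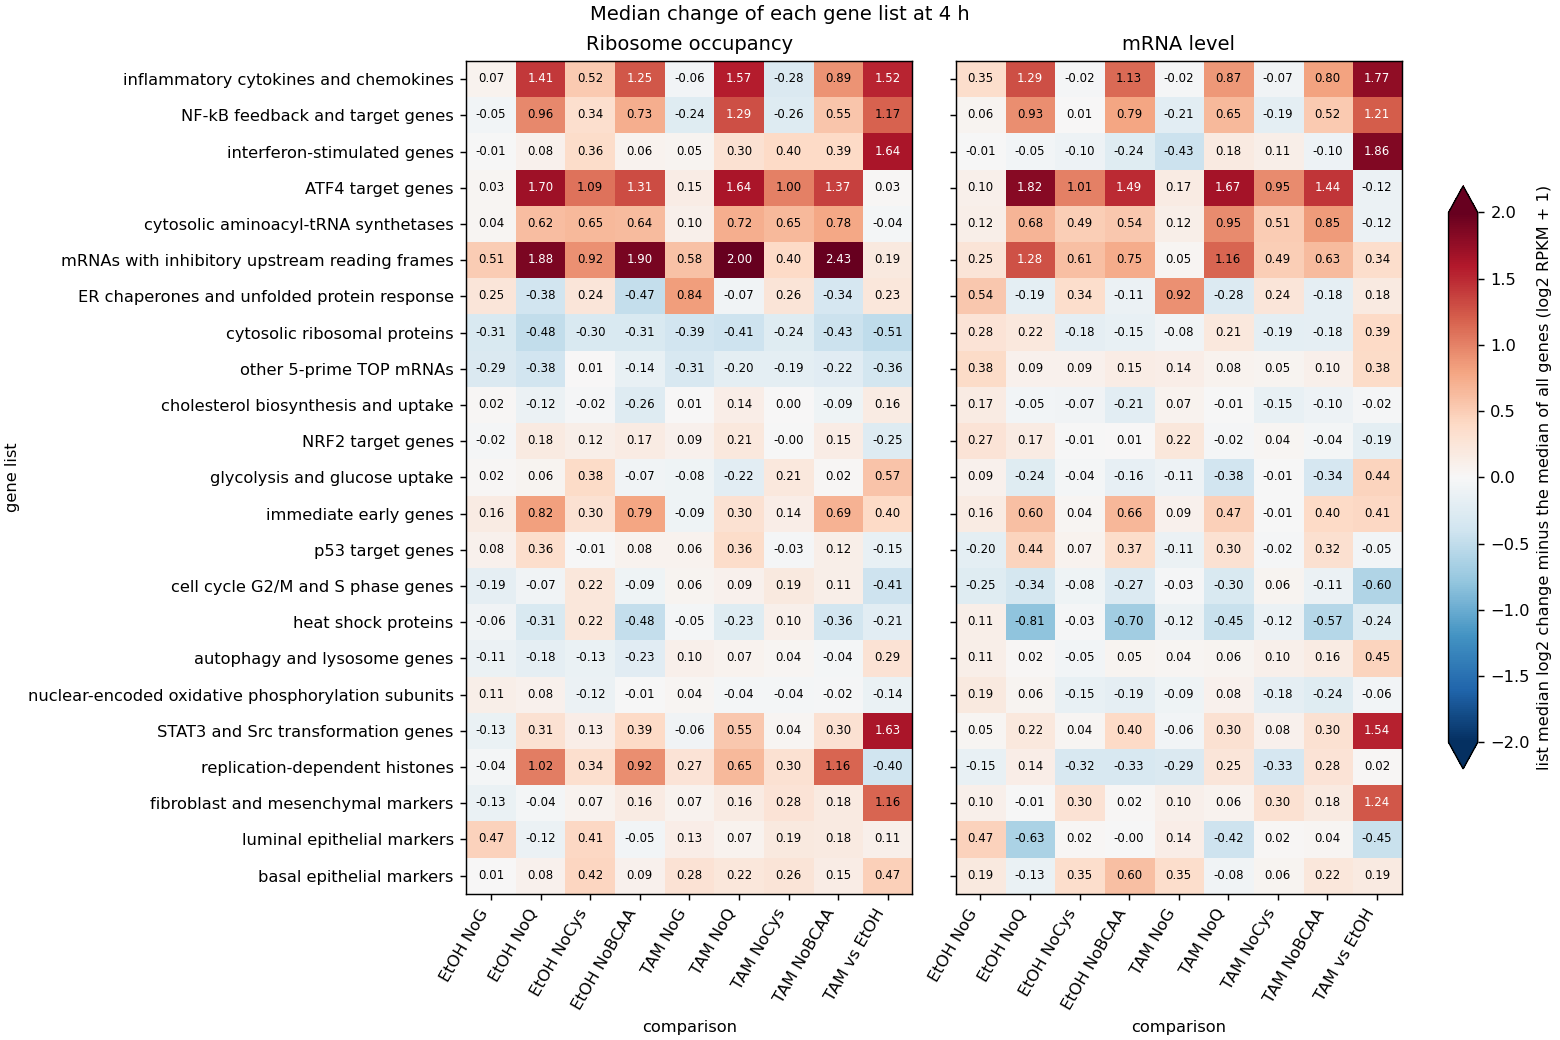
Heat map of list medians relative to the median of all genes (colour, log2, −2 to 2) for ribosome occupancy, left, and mRNA level, right; rows are the 23 tested gene lists and columns the starvations by cell state and TAM against EtOH. ATF4 targets stand at 1.70, 1.09 and 1.31 in ribosome occupancy of EtOH cells without glutamine, cysteine and branched-chain amino acids, and at 0.03 without glucose.

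Whether starvation acted differently in transformed cells was asked by comparing the changes of both states, which share no control library. In most starvations both states have the same uneven library numbers, so their changes are not independent of an effect of the number. Across genes, which are not independent replicates, the changes in ribosome occupancy correlated between EtOH and TAM cells with Pearson r of 0.48 for NoG, 0.67 for NoQ, 0.57 for NoCys and 0.72 for NoBCAA (Spearman 0.44, 0.58, 0.53 and 0.67). For mRNA the Pearson values were 0.45, 0.83, 0.78 and 0.85, and 0.47, 0.83, 0.67 and 0.83 with the library number as a block. Different starvations taken from different states gave 0.62 for NoQ in EtOH against NoBCAA in TAM cells and −0.03 for NoG in EtOH against NoQ in TAM cells. In the test of the difference itself, limma called 0 genes in ribosome occupancy for NoG, NoQ and NoBCAA, with 29, 85 and 47 genes at an unadjusted p under 0.05, and 2 for NoCys (PAX3 and SLCO1A2). That count was 0 without EtOH Ctrl library 3, EtOH NoCys library 1 or TAM Ctrl library 1. For NoQ the count was 12 without NoQ library 2 of TAM cells, and 1 or 2 without the EtOH NoQ libraries, TAM NoQ library 1 or TAM Ctrl library 1; for NoG it was 2 without TAM Ctrl library 1. For mRNA 2 genes differed for NoQ, the acetylcholine receptor subunit CHRNA9 at −2.08 ± 0.28 and the histone demethylase JHDM1D at −1.41 ± 0.22 (adjusted p = 0.0088 and 0.026), both named after their values were seen. Leaving out either TAM NoQ library gave 0 calls, leaving out EtOH NoQ library 2 gave 5, and 1 was called without EtOH NoQ library 1, EtOH Ctrl library 2 or 3, or any TAM Ctrl library. For NoG, NoCys and NoBCAA 0 mRNAs differed by limma, with 392, 28 and 224 at an unadjusted p under 0.05; 309 were called for NoG without NoG library 2 of EtOH cells. With the library number as a block 50, 22, 0 and 40 mRNAs differed for NoG, NoQ, NoCys and NoBCAA, and 46, 22, 0 and 34 with the block and scaling. In ribosome occupancy the block gave 2 for NoQ and 0 for the others. As lists, inflammatory genes differed in ribosome occupancy for NoQ (relative median 0.32, higher in TAM, adjusted p = 0.00014, and adjusted p = 0.42 with an estimated correlation). For NoBCAA they differed in the other direction (−0.41, adjusted p = 2.9e-05, and adjusted p = 0.3 with an estimated correlation). For NoCys they were also lower in TAM (relative median −0.74, adjusted p = 2.6e-23, held with an estimated correlation at 0.011), where the list median as measured was −0.34 and that of all genes 0.40. ER chaperones rose more without glucose in TAM than in EtOH cells in ribosome occupancy (relative median 0.43, adjusted p = 1.8e-09, and adjusted p = 0.71 with an estimated correlation). In mRNA the relative median of the difference was 0.18 (adjusted p = 0.0028, and adjusted p = 0.093 with an estimated correlation).

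Translation efficiency separates ribosome loading from mRNA level. ATF4 gained translation efficiency without branched-chain amino acids, by 2.57 ± 0.49 in EtOH and 2.79 ± 0.49 in TAM cells (adjusted p = 0.0096 and 0.0016). Without cysteine it gained 2.27 ± 0.47 and 2.67 ± 0.49 (adjusted p = 0.04 and 0.0043), and without glutamine it stood at 2.18 ± 0.49 and 2.03, not called. With the block and scaling ATF4 was called in each of these, at 2.18 to 2.68, and without glutamine at 2.30 and 2.41 (adjusted p = 1.4e-06 and 4.7e-07). C19orf48 and SERPINB4 were the others called, by 2.41 ± 0.49 and 2.97 ± 0.65 in EtOH cells without branched-chain amino acids. Calls without the block turned on single libraries while the value of ATF4 stayed between 2.10 and 2.97. In EtOH NoCys 0 were called without any 1 of the libraries except ribosome profiling NoCys 1, and in EtOH NoBCAA 0 without RNA-seq libraries Ctrl 1, NoBCAA 2 or NoBCAA 3. In TAM cells the calls ended without ribosome profiling library 2 or RNA-seq library 3 of NoCys, and likewise of NoBCAA. No other gene passed limma in the starvations or in TAM against EtOH, where 0 were called and 80 had an unadjusted p under 0.05. For NoG and NoQ 0 were called in both states, with 68 and 88 in EtOH and 18 and 224 in TAM cells at an unadjusted p under 0.05. Without NoQ library 2 of TAM cells 105 genes were called there. With the block, TAM against EtOH gave 0 up and 96 down. Ribosomal protein mRNAs, which carry 5-prime TOP motifs read by mTOR signalling, were lower in TAM than in EtOH cells in 76 of 76 cases. Their relative median was −0.94 (adjusted p = 3.2e-93, and adjusted p = 0.29 with an estimated correlation). Their mRNA median was 0.39 and their ribosome occupancy −0.51 relative to all genes, with 0 members called by limma in each. RPS6 as an example averaged 953.8 ± 370 RPKM of ribosome occupancy in EtOH and 498.7 ± 186 in TAM Ctrl cells (adjusted p = 0.27). With the block and scaling RPS6 was called lower in ribosome occupancy (−0.62, adjusted p = 0.00032) and translation efficiency (−0.95, adjusted p = 0.00027). RPS12, RPS27, RPS2 and RPL27A were likewise called in both. The list was also lower without glutamine, at −0.72 in EtOH and −0.62 in TAM cells (adjusted p = 2.7e-29 and 9.8e-20, and adjusted p = 0.94 and 1 with an estimated correlation). Without glucose it stood at −0.59 and −0.35 (adjusted p = 1.9e-38 and 1.8e-16, and adjusted p = 0.82 and 1 with an estimated correlation). Without cysteine or branched-chain amino acids it was not called in EtOH cells. Other TOP mRNAs stood at −0.73 in TAM against EtOH (adjusted p = 4.8e-22, and adjusted p = 0.46 with an estimated correlation). The mRNAs with inhibitory upstream reading frames were higher without branched-chain amino acids, by 0.35 and 0.64 (1 of 7 called in each state; adjusted p = 5.1e-05 and 3.2e-06, and adjusted p = 0.57 and 0.47 with an estimated correlation). Histones, whose mRNAs mostly lack poly(A) tails, were higher by 1.25 and 0.99 there (0 of 6 called by limma, 3 and 2 adjusted over the list alone; adjusted p = 7.2e-11 and 8.8e-07, and adjusted p = 0.29 and 0.57 with an estimated correlation).

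**Figure D4:**
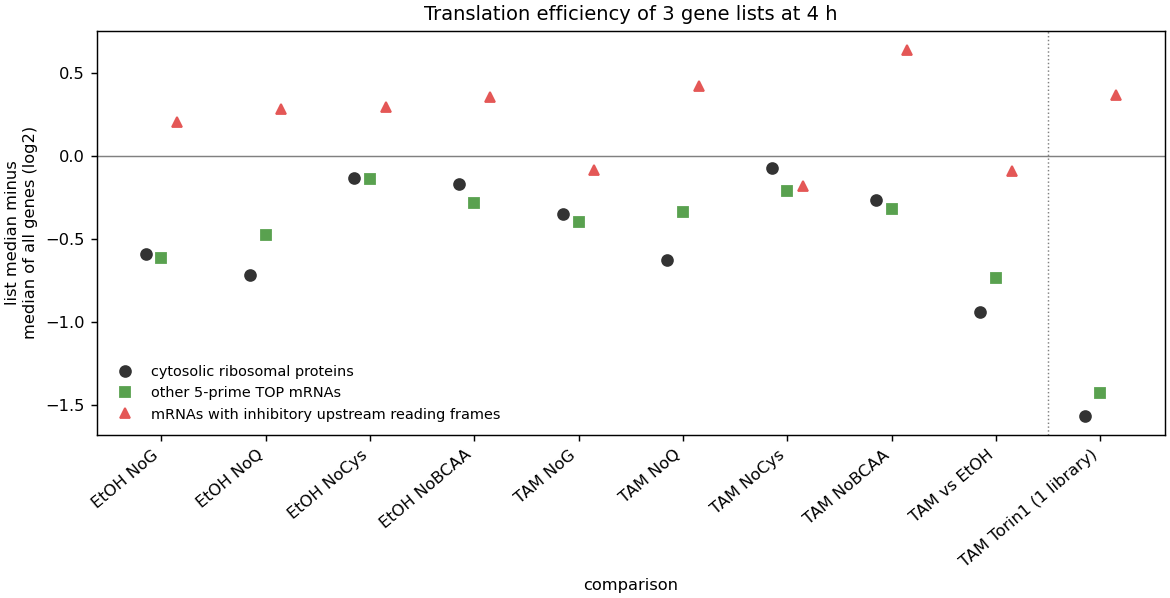
Median change in translation efficiency of 3 gene lists relative to all genes (vertical axis, log2) in 9 comparisons at 4 h and with Torin1. Ribosomal proteins stand at −0.94 in TAM against EtOH and −1.56 with Torin1, other TOP mRNAs at −0.73 and −1.42.

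Torin1, which blocks mTOR, served as a reference for mTOR-dependent translation in TAM cells. With 1 library per assay there is no replicate check, and values are against TAM Ctrl library 1. The median of all genes was −0.92 in ribosome occupancy and −0.14 in mRNA. In ribosome profiling the tabulated coding sequences held 11.4% of reads with Torin1 and 23.1% in Ctrl library 1. A general loss of ribosome occupancy therefore cannot be told apart from this difference in read share. Translation efficiency of ribosomal proteins was −1.56 relative to all genes (76 of 76 lower, percentile 0 among 10000 random lists) and of other TOP mRNAs −1.42 (17 of 17 lower). RPS6 had 73.4 RPKM in ribosome profiling with Torin1 and 292.7 without, a translation efficiency difference of −2.05, and the elongation factor EEF1A1 was at −2.25. ATF4 as measured was at −0.48 in ribosome occupancy, above the −0.92 of all genes, and at −0.94 against the mean of the 3 Ctrl libraries. Its translation efficiency was −0.40, where the median of all genes was −0.77. Inflammatory and NF-kB genes were higher in mRNA, by 0.89 and 0.96 relative to all genes (percentile 100 for each), and lower in translation efficiency, at −0.79 and −0.61 (percentiles 0.19 and 0.22). IL6 and IL8 mRNA differed by 1.79 and 1.63 and their translation efficiency by −1.06 and −1.44. IL6 had 3.8 RPKM in ribosome profiling with Torin1 and 1.9 without, where the scale understates changes, so its translation efficiency is uncertain. IL8 had 590.9 and 517 RPKM. Relative to all genes, heat shock mRNAs were at −0.62 (percentile 0), glycolysis mRNAs at −0.31 (percentile 0) and ER chaperone mRNAs at −0.30 (percentile 0.01).

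At 30 min the question is how fast ribosome occupancy responds to loss of glutamine. The 2 libraries of each group were nearly equal and are counted as 1 sample, so these are values without a test. ATF4 was already higher, at 147 against 25.7 RPKM in EtOH cells (log2 2.49) and 131 against 51.7 in TAM cells (1.34). Relative to all genes, ATF4 targets as a list were at 0.03 and 0.06, with TRIB3 at 0.53 and ASNS at −0.20 in EtOH cells. Ribosomal proteins were at −0.77 and −0.46 (percentile 0 in each, 0 of 75 higher), such as RPL12 at 279 against 886 RPKM in EtOH cells and RPS12 at −1.65 and −1.52. The mRNAs with inhibitory upstream reading frames were at 0.64 and 0.42 (percentiles 99.99 and 98.71), and inflammatory genes at 0.28 and −0.01 (percentiles 100 and 59.1). At least 2-fold differences were seen for 9 genes higher and 38 lower of 5696 in EtOH cells, and for 3 and 33 in TAM cells, or 10 and 25 after scaling. At a pseudocount of 0.1 the TAM counts were 12 and 47, and the number higher also rose when any 1 column was left out. Between TAM and EtOH cells in complete medium 368 were higher and 1261 lower, or 633 and 671 after scaling, with the median of all genes at −0.39. IL24 had 1819 against 3.95 RPKM, IL8 was at 2.67, CXCL1 at 2.53 and IL1B at 2.02. Inflammatory genes as a list stood at 3.06 (percentile 100) and cell cycle genes at −2.20 (percentile 0) relative to all genes. In the 4 h libraries the same contrast gave 0.58 for IL8, 1.63 for CXCL1 and 0.06 for IL1B. IL24 was at 8.52 at 30 min and 7.36 at 4 h, and SRC at −0.91 and 0.03. STC1 went the other way, at 7.40 and 8.30. The cause of these differences was not tested.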

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

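The tests of library scale and of the near-equal 30 min libraries were chosen only after the results were seen; the other tests in this part were written down first. Differences between cell states stood out in 5 results of the test of the difference itself. For cysteine starvation the effect on ribosome occupancy in TAM minus that in EtOH cells was −2.85 for PAX3 (adjusted p = 0.0027) and −3.42 for SLCO1A2 (adjusted p = 2.0e-05). Both genes were high in the 6 ribosome profiling libraries numbered 1 and close to 0 in the 18 others, TAM NoCys had no library numbered 1, and with the block 0 genes differed. The median of inflammatory cytokines and chemokines differed by −0.34 as measured, while that of all genes differed by 0.40 (adjusted p = 2.6e-23, and adjusted p = 0.011 with an estimated correlation, and 4.4e-08 with the block). For glutamine starvation the mRNA effect differed by −2.08 for CHRNA9 (adjusted p = 0.0088) and by −1.41 for JHDM1D (adjusted p = 0.026).

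With the library number as a block, 255 genes rose and 1295 fell in ribosome occupancy of EtOH cells without branched-chain amino acids. With scaling added to the block 44.6% of the called genes fell, but scaling sets the median of all genes close to 0 and so leaves little room for another share. The log2 ratio of the share of reads in tabulated coding sequences, −0.33, lay within 0.0387 of the median change of all genes, −0.29, but both values sum up the same libraries. Neither test can separate the explanations, so a difference of scale or of read share cannot be told apart from a change in the cells. A true loss of translation of most of these genes stays open and was not tested.

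Ribosomal protein mRNAs had a translation efficiency of −1.03 in TAM against EtOH cells, as measured. The list lay at percentile 0 of 10000 lists matched on broad classes of coding length and mRNA level, whose median was −0.16. The match within these classes is loose, so short coding sequences are argued against only at that resolution. The libraries numbered 1 are argued against as the whole source, since the list stood at −1.09 and −0.77 relative to all genes in numbers 2 and 3. Lower mTOR activity in TAM cells might lower this list as Torin1 did, and the correlation of both changes across 6373 genes outside the TOP lists, r = 0.171, lay between the bounds of 0.1 and 0.2 set for either outcome. That explanation therefore cannot be told apart from its absence, and with an estimated correlation the list was not called (adjusted p = 0.29).

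The 2 ribosome profiling libraries of each 30 min group differed by a robust SD of at most 0.106 of that expected from counting error, and 13% to 22% of genes had identical values. Depth was recovered only for the library numbered 1 of each pair, so the counting error assumes the same depth for its partner. The pairs of 4 h ribosome profiling libraries differed by at least 1.53 times the counting error. A candidate explanation is that largely the same reads stand behind both columns of each pair. Separate cultures, or a library split into separate reads, with so little spread would need reads that vary less than by chance. No biological explanation was tested.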

How the results depend on the processing

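The block together with scaling, and libraries numbered 2 and 3 only, were chosen after seeing the data. In ribosome occupancy simulated with the fitted spread of each gene, for glutamine-starved EtOH cells, log2 changes of 1 were recovered in 13.4% of genes and changes of 2 in 92.5%. Where leaving out a library left 1 in a group, limma assumed that it varies like the other groups. Counts below are genes called, with the main count first; the cause was not tested for any of the changes. In groups with 2 numbers in common, deviations of libraries with the same number correlated at r of −0.06 to 0.82. For the 30 min comparisons and Torin1, no paired analysis was possible because each group held 1 sample. With no filter every count of genes remained within 1.5 times its main value. The 30 min counts of 47 for EtOH NoQ and 1629 for TAM against EtOH ranged from 37 to 56 and from 1304 to 1732, and the median correlation of states, 0.62, from 0.61 to 0.66. The Torin1 value of ribosomal proteins, −1.56, was −1.46 at a pseudocount of 0.1 and −1.99 against the mean of 3 Ctrl libraries. Of 2876 values of named genes, 2365 kept their direction and side of the threshold with scaling, 2816 with a pseudocount of 0.1, 2876 with no filter and 2049 with the block, where 414 passed newly and 3 no longer. Values called under neither setting changed direction in 271, 35, 0 and 408 cases. With the ratio per library number 930 of 956 kept both, 24 uncalled values changed direction and 2 no longer passed. In libraries 2 and 3 only these counts were 691, 94 and 19, and 152 passed newly.

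With scaling, ribosome occupancy counts went for EtOH NoG from 4 to 16, NoQ 64 to 404, NoCys 10 to 56 and NoBCAA 92 to 833. In TAM cells NoG went from 8 to 33, NoQ 50 to 472 and NoBCAA 37 to 367, and TAM against EtOH went from 379 to 1120. Differences between states went from 0 to 2 for NoQ and from 2 to 0 for NoCys. For mRNA, EtOH NoG went from 407 to 212, the NoG difference from 0 to 3 and the NoQ difference from 2 to 1. For translation efficiency, EtOH NoQ went from 0 to 6, EtOH NoBCAA 3 to 10, TAM NoQ 0 to 1, TAM NoBCAA 1 to 3 and TAM against EtOH 0 to 7.

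With the replicate block, ribosome occupancy gave 19, 366, 44 and 1550 for EtOH NoG, NoQ, NoCys and NoBCAA, 84, 864 and 1158 for TAM NoG, NoQ and NoBCAA, and 2064 for TAM against EtOH. The NoQ difference gave 2 and the NoCys difference 0. For mRNA (main counts 407, 716, 33, 1001, 100, 500, 28, 980 and 2292) it gave 1721, 1828, 117 and 2170 in EtOH cells for NoG, NoQ, NoCys and NoBCAA. It gave 506, 1511, 60 and 2471 in TAM cells and 3748 for TAM against EtOH. Differences in mRNA gave 50 for NoG, 22 for NoQ and 40 for NoBCAA. For translation efficiency the block gave 26, 11 and 253 for EtOH NoG, NoQ and NoBCAA, 47 and 93 for TAM NoQ and NoBCAA, and 96 for TAM against EtOH.

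With the replicate block and scaling, ribosome occupancy gave 21, 496, 118 and 1062 in EtOH cells for NoG, NoQ, NoCys and NoBCAA, 83, 700, 26 and 532 in TAM cells, and 1311 for TAM against EtOH. The differences gave 4 for NoQ, 0 for NoCys and 2 for NoBCAA. For mRNA it gave 1751, 1813, 125 and 2138 in EtOH and 491, 1464, 60 and 2122 in TAM cells, with differences of 46 for NoG, 22 for NoQ and 34 for NoBCAA. For translation efficiency it gave 10, 25 and 40 for EtOH NoG, NoQ and NoBCAA, 8 and 36 for TAM NoQ and NoBCAA, and 85 for TAM against EtOH. In libraries numbered 2 and 3 only, ribosome occupancy gave 12, 44 and 1459 for EtOH NoG, NoCys and NoBCAA, 55 and 800 for TAM NoG and NoBCAA, and 1495 for TAM against EtOH.

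At a pseudocount of 0.1, ribosome occupancy went from 8 to 2 for TAM NoG, from 2 to 0 for the NoCys difference, and from 36 to 59 for TAM NoQ at 30 min, a count of genes with at least 2-fold differences. With an estimated correlation, list calls over the 3 measures went from 304 to 39, of which 16 were in ribosome occupancy, 23 in mRNA and 0 in translation efficiency. The correlation was estimated in the main fit only, which leaves out the library number, so shifts by number can enter it. It was not estimated with the block. They were 296 to 329 under the other settings.

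Leaving out each library in turn, ribosome occupancy counts ranged for EtOH NoG from 0 to 3, NoQ 21 to 70, NoCys 6 to 29 and NoBCAA 30 to 87. For TAM they ranged from 0 to 7 for NoG, 26 to 360 for NoQ, 4 to 19 for NoCys and 17 to 39 for NoBCAA, and from 295 to 634 for TAM against EtOH. Differences between states ranged from 0 to 2 for NoG, 0 to 12 for NoQ and 0 to 2 for NoCys. For mRNA the ranges in EtOH cells were 11 to 1188 for NoG, 225 to 610 for NoQ, 11 to 31 for NoCys and 346 to 951 for NoBCAA. In TAM cells they were 7 to 73, 131 to 504, 12 to 25 and 241 to 1157. Differences in mRNA ranged from 0 to 309 for NoG, 0 to 5 for NoQ and 0 to 1 for NoBCAA, and TAM against EtOH from 1833 to 2224. For translation efficiency the ranges were 0 to 1 for EtOH NoG, 0 to 1 for EtOH NoCys, 0 to 5 for EtOH NoBCAA, 0 to 105 for TAM NoQ, 0 to 1 for TAM NoCys and 0 to 1 for TAM NoBCAA. The highest counts without TAM NoQ library 2 were the 360 and 105 for TAM NoQ and the 12 of its difference, and without EtOH NoG library 2 the 1188 and 309 in mRNA.

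Among values called under either setting, direction reversed for 2 genes. PAX3 in TAM cells went from −1.89 to 0.029 with the replicate block for NoG and for NoBCAA, and to 0.0013 and 0.027 with the replicate block and scaling. PAX3 was at −2.89 without TAM Ctrl replicate 2 and at 0.058 without TAM Ctrl replicate 1 in each comparison. SLCO1A2 in EtOH NoCys cells went from 0.83 to −1.75 without EtOH NoCys replicate 1, and SLCO1A2 was at 2.65 without EtOH Ctrl replicate 1.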

Other observations

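Of the tests in this part, only the comparison of splits that part every pair was chosen after the result was seen. Nuclear-encoded oxidative phosphorylation genes were called as a list in no comparison of ribosome occupancy between media or cell states. Their mRNAs were lower without branched-chain amino acids (relative medians −0.19 in EtOH and −0.24 in TAM cells; 0 and 2 of 30 members called by limma; adjusted p = 0.039 and 0.0073, and adjusted p = 0.92 and 0.88 with an estimated correlation). Of the mitochondrially encoded genes 0 of 13 were in the table. Histones were higher in ribosome occupancy without glutamine in EtOH cells, at 1.02 (0 of 6 called by limma, 3 adjusted over the list alone; adjusted p = 7.7e-06, and adjusted p = 0.53 with an estimated correlation). Without branched-chain amino acids they stood at 0.92 in EtOH and 1.16 in TAM cells (0 of 6 called by limma in each; adjusted p = 0.00078 and 4.1e-08, and adjusted p = 0.87 and 0.28 with an estimated correlation). Luminal markers were higher in EtOH cells without glucose, at 0.47 (0 of 7 called by limma; adjusted p = 6e-05, and adjusted p = 0.53 with an estimated correlation). Basal markers were higher in ribosome occupancy without cysteine, at 0.42 in EtOH and 0.26 in TAM cells (0 of 13 called by limma; adjusted p = 0.00014 and 0.0017, and adjusted p = 1 in each with an estimated correlation). Fibroblast and mesenchymal marker mRNAs were higher in TAM than EtOH cells, at 1.24 (3 of 5 higher and 1 lower; adjusted p = 0.05, and adjusted p = 0.28 with an estimated correlation). CD14, a leukocyte marker, fell by 0.88 in mRNA of TAM cells without branched-chain amino acids and was at −0.28 in EtOH cells. KLF10, the other MondoA/ChREBP target measured, rose by 0.78 in EtOH mRNA there and by 1.10 in TAM against EtOH. In unstarved cells 15 of 34 ATF4 target mRNAs were lower and 6 higher in TAM than EtOH cells, with no list call (adjusted p = 0.72), while 1649 of all 6476 genes were lower; ASNS was at −0.94 and TRIB3 at −0.91. Aminoacyl-tRNA synthetase mRNAs fell in 9 of 19 cases there (adjusted p = 0.061 as a list).

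The authors' deposited table marks 184 genes as higher and 156 as lower in ribosome occupancy of EtOH cells without glutamine. Of these 56 and 3 were called here, and 164 and 94 with the library number as a block. For branched-chain amino acids in EtOH cells the authors' deposited table marks 140 higher and 1167 lower, of which 72 and 8 were called here, and 138 and 959 with the block. In the authors' deposited table Torin1 has 4 genes marked higher and 2001 lower. For glutamine starvation at 30 min the authors' deposited table marks 17 higher and 147 lower in EtOH cells and 27 and 158 in TAM cells. RNA-seq at 30 min was labelled for the glutamine-free medium only. Rounded RPKM in EtOH and TAM cells were 520 and 533 for ATF4, 213 and 547 for CXCL1, 88 and 375 for IL1B, 113 and 214 for IL8, and 3175 and 3517 for RPS6.

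The same 6 libraries can be split into 3 against 3 in 10 ways, the real one included, too few for a share under 0.05. For cysteine starvation of EtOH cells the real split called 10 genes in ribosome occupancy and the highest other split 28, and 4 splits, the real one included, called at least as many. Among the 3 other splits that part every pair of libraries with the same number, the highest called 1. The splits with both libraries numbered 1 on the same side called 9, 13, 28 and 26, which points to a structure of the samples by number, and with the block 37 rose and 7 fell. For TAM against EtOH the real split called 379 genes in ribosome occupancy and the highest other 2, so only the real 1 of the splits called as many. For mRNA level these values were 2292 and 0, again 1 split. For translation efficiency 0 were called by limma in the real split, with 80 genes at an unadjusted p under 0.05, and 49 in the highest other. With a real count of 0, each of the 10 splits reaches it whatever the data, so this comparison decides nothing.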
